A study of Mus musculus with 10 samples.

How the data were processed

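The series holds 8 bulk RNA-seq libraries and a single-cell RNA library with its hashtag library, 10 samples in all. Groups were taken from the labels alone. The bulk libraries are CD4 T cells and MAIT cells of control or S. epidermidis-associated mouse skin, 2 per group. The labels do not say whether libraries of a group come from separate animals, so p-values measure only the spread between these samples. RNA input was 100 ng per library, per the labels' protocols.

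The bulk values were deposited as RPKM for each gene, per the file headers, and the submitters' processing notes name STAR, HOMER and DESeq2 for bulk data and the mm10 genome build. Coordinates are 1-based mm10. The single-cell library was deposited as UMI counts for 737280 barcodes and 27998 features and for 6463 called cells, with Cell Ranger 3.0.1 and Seurat 3.0 named in the submitters' processing notes, and the hashtag library as counts for 2000 barcodes and 4 tags. In every bulk file the value times the gene's length is a whole multiple of a step of 40.9 to 55.5, within 0.1 of a whole number for 99.3% to 100% of the values tested. The total that this step implies lies below the sum of the multiples in all 8 libraries, so the number of reads behind a value is not known and no counting interval is given for bulk values. The counting covers whole gene spans, and 3620 genes overlap another gene that gives at least 20% of their reads. For 1128 genes the span differs between files. The 436 of these above the filter were left out of the test after values had been seen, and list members lost this way include Il4, Il1rl1, Il18r1, Nr4a3, Mx1, Dcn and Pdgfra. The files turn 26 gene symbols into dates.

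Bulk values were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with all 8 libraries in 1 fit of 4 group means, an intensity trend (4 residual degrees of freedom, prior 3.06), and Benjamini-Hochberg adjusted p under 0.05 in each of 5 comparisons. The planned test was edgeR on counts, with this limma fit as the stated replacement where files hold no counts. Genes entered at 1 RPKM or more in at least 2 libraries, which left 11459. Fold changes on this scale understate changes of genes with low values. With 2 libraries against 2, permutation p-values cannot go below 0.33, so none are given. On simulated data for the MAIT comparison (11459 genes), 200 genes with a mean above 10 RPKM were changed. The test found 65 of 100 genes changed by 1 log2 and 94 of 100 changed by 2 log2, with 2 false calls among 161. The edgeR alternative (14343 genes), with changes placed in genes above 1 CPM, found 30 and 63 of 100, with 6 false calls among 99. The floors differ, so the tests cannot be ranked by these rates. Recovery of changes below 10 RPKM was not simulated for limma.

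Gene lists, group definitions, thresholds and the rule for named genes were fixed before the data were examined. Of 29 lists, 23 had enough members above the filter and were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. No precision weights were used, since there were no counts. An estimated correlation and fry were alternatives, and no list passed camera in any comparison with an estimated correlation. The lists are type 17, type 1 and cytotoxic, type 2, tissue repair and growth factors, IL-1 and IL-18 receptor signalling, T cell activation, proliferation, tissue residency, naive and circulating T cell, interferon-stimulated, innate-like T cell, sorted T cell markers, lipid metabolism, glycolysis and hypoxia, dissociation stress, regulatory T cell, NK cell and innate lymphoid, macrophage with dendritic and Langerhans cell, neutrophil, mast cell, keratinocyte, fibroblast and endothelial. "Adjusted over the list alone" counts members past the test when only the list's genes are adjusted. Named genes are, per comparison, the 12 with the largest log2 change in each direction among called genes with a mean of at least 10 RPKM in the higher group and no overlap between the groups' libraries, and in each list up to 4 members with the smallest p. For every named gene called between 2 groups, both libraries of the higher group lay above both of the lower. T cell receptor and immunoglobulin segments, mitochondrial genes and unnamed loci were counted and not named. Il17a, Il17f and Il22 in MAIT cells and in the interaction were added after their values were seen.

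Alternatives were quantile normalization, a pseudocount of 0.1, no filter, a fit of only the 2 groups, a block for replicate number, and leaving out each library. Added after the data were seen were edgeR 4.0.16, limma-voom and DESeq2 1.42.0 on the recovered multiples, genes of differing span kept, overlapping genes left out, a filter on genes read at 5 CPM or more in single MAIT cells, leaving out 107 genes of macrophage-like single cells, and the macrophage list mean as a covariate.

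Single cells were analysed with scanpy 1.11.5 in Python 3.11.15. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept (6162, with 301 left out), and clustered on 2000 variable genes, 20 principal components and 15 neighbours with Leiden at resolution 0.5, which gave 12 clusters. A cluster was named, with the suffix "-like", by marker lists fixed beforehand. Hashtags were called with HTODemux in Seurat 5.3.0 at a positive quantile of 0.99. Of 997 hashtag barcodes among called cells, 887 (89%) had 1 tag, 71 had several and 39 none, and 5466 called cells had no hashtag barcode. The doublet caller scrublet marked 2 cells (0.03%) against 71 hashtag doublets and was not used. CPM are UMIs summed over the cells of a tag and scaled to the tag's total, with exact Poisson 95% intervals, and shares have exact Clopper-Pearson 95% intervals. The limit given for a count of 0 is 3 counts over the number of cells, slightly below the upper end of the exact interval. Summed UMIs were 2085712 for HTO1, 43435 for HTO2, 828836 for HTO3 and 1089388 for HTO4, with medians per cell of 5204.5, 3586, 3435 and 3697.5. A gene was named for a tag if it had at least 100 UMIs, a UMI in at least 10% of cells, and an interval above all other tags, taking the 10 largest ratios. In 5 of the lists the members with the 4 largest ranges over HTO1, HTO3 and HTO4 were named, and HTO2 was left out of the range after its 11 cells were seen. No test was made between tags.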

Results

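Gene expression was measured in T cells from mouse skin and in single MAIT cells from several organs, in 10 samples. MAIT cells (mucosal-associated invariant T cells) carry a semi-invariant T cell receptor that binds microbial vitamin B2 metabolites on MR1. The 8 bulk RNA-seq libraries came from female C57BL/6NTac mice aged 7 weeks at the start. They form 4 groups of 2 libraries, CD4 T cells or MAIT cells from control skin or from skin to which the commensal Staphylococcus epidermidis LM061 had been applied on days 0, 2, 4 and 6, with harvest on day 14. MAIT cells were sorted with MR1 tetramers and CD4 T cells as tetramer-negative, CD4+, CD8b- and CD25- cells. Each bulk library lists 24537 genes in RPKM (reads per kilobase of gene, scaled to the library), of which 14438 to 15829 were above 0 and 10500 to 11089 reached 1. Read totals are not given in the sources used here. Summed RPKM was 666701 to 680282 per library, and the 10 most abundant genes held 13.7% to 16.0% of it. A 10x single-cell library held 6463 called cells (30705716 UMIs, median 4354 UMIs and 1624 genes per cell) of control mice, pooled from skin, spleen, lung and liver. A hashtag library with 4 antibody tags accompanied it, and the sources used here do not say which tag marks which organ, so cells are reported by tag name.

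Cd4 and Zbtb16 separated the cell types in every bulk library, while Il2ra and Cd8b1 overlapped between the sorts. Cd4 (chromosome 6, 124864693 to 124888209, mm10) stood at 171 ± 22.9 RPKM in CD4 T cells of control skin and 243 ± 10.4 RPKM after S. epidermidis (mean ± SD, n = 2 here and throughout). In MAIT cells Cd4 stood at 0.1005 ± 0.1351 and 2.55 ± 0.129 RPKM. Zbtb16, which encodes the innate-like T cell regulator PLZF, was at 5.69 ± 1.69 and 4.13 ± 0.156 RPKM in control and S. epidermidis MAIT cells, against 0.3265 ± 0.3712 and 0.0585 ± 0.0177 RPKM in CD4 T cells. Cd3e was high in all 4 groups, at 361 ± 24.0 and 302 ± 6.86 RPKM in CD4 T cells and 285 ± 12.5 and 233.0 ± 30.1 RPKM in MAIT cells. Il2ra, the gene of CD25, was read at 44.2 ± 0.564 and 49.6 ± 8.53 RPKM in the CD25-negative CD4 sort, and at 106 ± 26.7 and 56.3 ± 0.924 RPKM in MAIT cells. Cd8b1 lay between 4.75 ± 0.413 and 7.72 ± 3.18 RPKM in the 4 groups. Across genes, replicates correlated at 0.969 to 0.985 and libraries of different groups at 0.876 to 0.956. Genes are not independent replicates. The first principal component took 47% of the variance and the second 23.7%.

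The first comparison asked what S. epidermidis association changed in skin MAIT cells. Transcripts of macrophages were higher after association by the widest margins. C1qa (chromosome 4, 136895916 to 136898844) and C1qb, subunits of complement C1q, rose from 30.1 ± 11.2 to 1119 ± 18.4 RPKM (log2 change 5.22, SE 0.29, adjusted p = 0.000222) and from 51.4 ± 15.3 to 1493 ± 163.5 RPKM (log2 change 4.86, SE 0.22, adjusted p = 0.000125). Egr1 (chromosome 18, 34861207 to 34864956), a transcription factor induced by receptor signalling, rose from 52.4 ± 2.31 to 567 ± 73.5 RPKM (log2 change 3.41, SE 0.11, adjusted p = 4.33e-05), and the AP-1 subunit gene Jun rose from 152 ± 1.29 to 820.3 ± 78.6 RPKM (adjusted p = 0.00747). In the single-cell library Egr1 stood at 10.8 CPM in MAIT cells of control mice and at 15 in empty barcodes. Which cells carried it in the bulk libraries is not shown. Tnfsf11, the gene of RANKL, fell from 105 ± 0.960 to 42.8 ± 8.51 RPKM (log2 change -1.29, adjusted p = 0.00833) and Bcl2, a survival gene, from 83.8 ± 0.153 to 41.3 ± 7.66 RPKM (log2 change -1.01, adjusted p = 0.0089).

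Among the other named genes that rose in MAIT cells were the chemokine genes Ccl8 (13.1 to 1162 RPKM, log2 change 6.52), Ccl12 (log2 change 5.94) and Ccl3 (3.62 to 203.5 RPKM, log2 change 5.49), the scavenger receptor gene Cd163 (2.74 to 145 RPKM) and the lectin genes Cd209f and Cd209g (log2 changes 5.79 and 5.22). Retnla (log2 change 8.20) and Pf4 (5.28) passed the test too, but only in 9 and 8 of 20 alternative settings. The list of macrophage, dendritic and Langerhans cell genes had 10 of 15 measured members higher and 0 lower (14 adjusted over the list alone, median log2 change 3.31). Its adjusted p in the limma set test camera was 6.3e-16, and the adjusted p = 0.24 with an estimated correlation. Cd68 rose from 77.1 ± 7.42 to 1201 ± 254 RPKM. In the list of NK cell and innate lymphoid genes, 3 of 5 rose (4 adjusted over the list alone, median 1.66, adjusted p = 0.0151, adjusted p = 0.556 with an estimated correlation). Its risen members Fcer1g and Tyrobp encode signalling adaptors that myeloid cells share. The neutrophil list had 2 of 5 higher (2 adjusted over the list alone, median 1.33, adjusted p = 0.195).

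Interferon-stimulated genes rose as a list in MAIT cells (median 0.62, adjusted p = 3.18e-05, adjusted p = 0.556 with an estimated correlation), with 3 of 19 members past the test upward and 1 downward, and 12 adjusted over the list alone. Rtp4 rose from 4.07 to 20.8 RPKM and Irf7 fell (log2 change -0.68, adjusted p = 0.0419), the latter in only 8 of 22 alternative settings. The macrophage list moved with this group, at a median of 3.31. In the T cell activation list 3 of 21 members rose and 5 fell (12 adjusted over the list alone, median -0.34, mean 0.07, test downward, adjusted p = 0.698). Egr1, Egr2 (35.8 to 158 RPKM) and the checkpoint receptor gene Ctla4 (2.33 to 13.1 RPKM) rose, while Tnfrsf9 (-0.87) and Cd69 (-0.49) fell. Cd4, the marker of the other sort, moved with them in the MAIT libraries, from 0.1005 to 2.548 RPKM (log2 change 1.69, adjusted p = 0.000913), as did Cxcr3 (1.80), Cd200r1 (2.2) and Il10 (2.19), which like Ctla4 stood higher in the CD4 libraries. Of the naive and circulating T cell genes, 3 of 15 rose and 1 fell (4 adjusted over the list alone, median -0.17, mean 0.28, test upward, adjusted p = 0.722). Klf2, a regulator of T cell egress, rose from 56.3 ± 5.40 to 177 ± 28.2 RPKM and Tcf7 fell from 115 ± 12.1 to 69.3 ± 3.23 RPKM. Of the 20 type 17 genes, 0 rose and 1 fell (1 adjusted over the list alone, median -0.21, adjusted p = 0.722). The fallen gene was Serpinb1a, a protease inhibitor, from 603 ± 27.1 to 374 ± 14.8 RPKM (adjusted p = 0.0107). The type 17 cytokine genes did not pass the test, Il17a at 4.07 ± 0.00990 and 9.02 ± 0.122 RPKM and Il17f at 33.5 ± 23.6 and 63.7 ± 17.1 RPKM.

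The remaining lists did not pass the set test in MAIT cells. Type 1 and cytotoxic genes had 3 of 18 higher and 2 lower (8 adjusted over the list alone, median -0.20, mean 0.37, test upward, adjusted p = 0.878), with Ccl3 and Ccl4 higher and Klrk1 lower. Tissue repair genes had 2 of 23 higher and 1 lower (6 adjusted over the list alone, median -0.17, mean 0.20, test upward, adjusted p = 0.726). Residency genes had 1 of 16 higher and 1 lower (5 adjusted over the list alone, median -0.08, mean 0.03, test downward). Dissociation stress genes had 4 of 18 higher and 3 lower (9 adjusted over the list alone, median -0.01, mean 0.33, test upward), and regulatory T cell genes 3 of 9 higher and 3 lower (6 adjusted over the list alone, median -0.03, mean 0.28, test upward). Medians of the type 2, IL-1 and IL-18 receptor, proliferation, innate-like T cell, sorted T cell marker, lipid and glycolysis lists were -0.35, -0.19, -0.03, -0.34, -0.29, -0.27 and -0.16. Those of the mast cell (mean 0.09, test upward), keratinocyte, fibroblast and endothelial lists were -0.08, -0.29, -0.48 and -1.13.

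In all, limma called 882 of 11459 genes in MAIT cells, 650 higher and 232 lower after association (73.7% higher), at a Benjamini-Hochberg adjusted p under 0.05, and 2615 had an unadjusted p under 0.05. The median change of all genes was -0.107 log2. The share of calls that were higher was 86.8% with edgeR and TMM scaling (401 higher, 61 lower), 87.8% with RLE scaling and 83.8% with limma-voom. Restricted to the 7763 genes read at 5 CPM or more in the single MAIT cells, the calls numbered 395, of which 201 were higher and 194 lower. The count was 490 without the second MAIT control library, 458 without the first and 372 without the second S. epidermidis MAIT library, and 1487 with DESeq2.

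**Figure D1:**
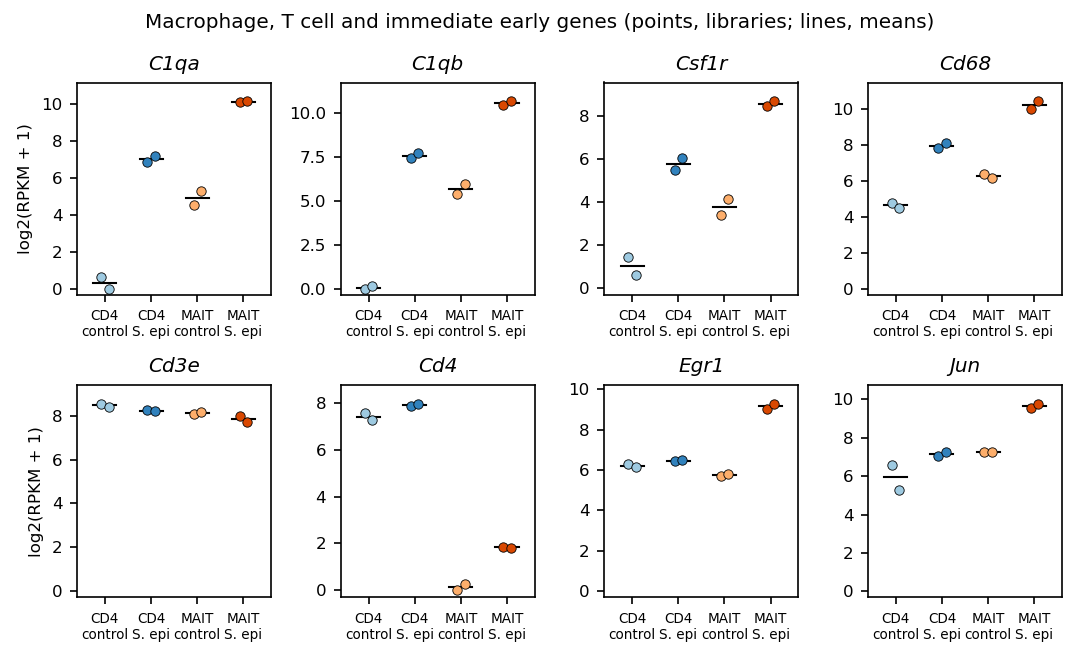
Expression of C1qa, C1qb, Csf1r, Cd68, Cd3e, Cd4, Egr1 and Jun in the 4 bulk groups (x axis), as log2(RPKM + 1) (y axis), with a point per library and a line at each group mean. C1qa rises from 30.1 to 1119 RPKM in MAIT cells, while Cd3e stays between 233.0 and 361 RPKM.

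The second comparison asked what the same association changed in skin CD4 T cells. Type 17 cytokine genes rose. Il17a (chromosome 1, 20730905 to 20734496) rose from 2.68 ± 1.39 to 27.0 ± 10.4 RPKM (log2 change 2.93, SE 0.33, adjusted p = 0.00912), Il17f from 27.3 ± 0.247 to 383 ± 53.2 RPKM (log2 change 3.76, SE 0.45, adjusted p = 0.00975) and Il22, a cytokine that acts on epithelium, from 3.41 ± 1.24 to 69.0 ± 3.03 RPKM (log2 change 4.01, SE 0.66, adjusted p = 0.0281). Macrophage genes were higher here too, with C1qb at 171 and 213 RPKM after association and at 0 and 0.151 RPKM in control libraries. Malat1, a nuclear long non-coding RNA, fell from 1202 ± 0.542 to 577 ± 21.1 RPKM (log2 change -1.06, adjusted p = 0.00963). Bcl2 fell from 69.3 ± 8.92 to 35.6 ± 2.86 RPKM (log2 change -0.94, adjusted p = 0.0282).

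Of the 20 type 17 genes, 8 rose in CD4 T cells and 1 fell (13 adjusted over the list alone, median 0.66, adjusted p = 0.00037, adjusted p = 0.369 with an estimated correlation). Besides the cytokines, Il17re, a subunit of the IL-17C receptor, rose from 10.7 to 29.9 RPKM and Il1r1 from 0.754 to 5.65 RPKM, the latter in only 8 of 22 alternative settings. The syndecan gene Sdc1 fell from 9.64 to 5.37 RPKM. Proliferation genes rose as a list (3 of 26 members, 13 adjusted over the list alone, median 0.58, adjusted p = 4.38e-07, adjusted p = 0.523 with an estimated correlation). Top2a rose from 26.6 ± 3.14 to 58.9 ± 2.98 RPKM and Mki67 from 19.8 ± 5.38 to 42.8 ± 1.96 RPKM, the latter in 11 of 22 settings. In the tissue repair list 3 of 23 rose (7 adjusted over the list alone, median 0.52, adjusted p = 0.0195, adjusted p = 0.369 with an estimated correlation), among them the protease gene Furin, from 300.4 ± 25.4 to 684 ± 105 RPKM. The macrophage list moved with these groups, with 9 of 15 members higher (10 adjusted over the list alone, median 1.68, adjusted p = 4.35e-07, adjusted p = 0.369 with an estimated correlation). Csf1r (log2 change 4.72) and Cd68 (24.4 to 250.4 RPKM) were among them, and the chemokine genes Ccl2 (4.38 to 419 RPKM) and Ccl4 (1.82 to 139 RPKM) rose as well. Mast cell protease genes Mcpt4, Cma1 and Tpsb2 were listed at 0 in the control libraries and had means of 7.00, 9.16 and 11.3 RPKM after association (3 of 7 list members higher, 4 adjusted over the list alone, median 2.22, adjusted p = 0.00488, adjusted p = 0.523 with an estimated correlation).

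The naive and circulating list was lower in CD4 T cells (median -0.27, adjusted p = 0.0195, adjusted p = 0.644 with an estimated correlation), with 0 of 15 members past the test and 0 adjusted over the list alone. The NK cell list was higher (median 0.81, adjusted p = 0.0195, adjusted p = 0.523 with an estimated correlation) with 1 of 5 members past the test, Fcer1g, and 2 adjusted over the list alone. Residency genes had 3 of 16 members higher and 1 lower (6 adjusted over the list alone, median 0.42, adjusted p = 0.0849). Itgae, the CD103 integrin chain, rose from 48.9 ± 4.10 to 77.0 ± 4.10 RPKM, in 11 of 22 settings. Tnf rose from 56.1 ± 2.31 to 141 ± 27.4 RPKM (adjusted p = 0.0074) in a T cell activation list with no other call (5 adjusted over the list alone, median 0.10, adjusted p = 0.969). Type 1 genes had 2 of 18 higher, the chemokine genes Ccl3 and Ccl4 (5 adjusted over the list alone, median 0.29, adjusted p = 0.16). The lists of interferon-stimulated, type 2, lipid, glycolysis, dissociation stress (mean 0.14, test downward) and regulatory T cell genes (mean 0.02, test downward) had medians of 0.08, -0.36, 0.38, 0.21, -0.11 and 0.15. None of these 6 passed. The innate-like (mean 0.02, test downward), IL-1 and IL-18 receptor, sorted T cell marker, neutrophil, keratinocyte, fibroblast and endothelial lists did not pass either, at -0.07, 0.01, 0.18, 1.07, -0.18, 1.02 and 0.73.

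In CD4 T cells limma called 437 genes, 347 higher and 90 lower (79.4% higher), and 2680 had an unadjusted p under 0.05. Quantile normalization gave 225 higher and 116 lower (66% higher). The count was 57 and 42 without the first and the second S. epidermidis CD4 library, 172 without the second CD4 control library, 195 without either S. epidermidis MAIT library, 48 with only the 2 groups in the fit and 2055 with DESeq2. Without the second S. epidermidis CD4 library neither Il17a (log2 change 2.54) nor Il17f (3.62) passed. Without the first, Il17f did not pass (3.90), and Il22 did not pass without any 1 of the 4 CD4 libraries (3.73 to 4.30). None of the 3 passed without a filter on expression, Il17a did not pass with only the 2 groups in the fit (2.93), and Il22 did not pass with limma-voom (4.29).

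The MAIT and CD4 responses shared 151 higher genes, out of 650 and 347, where 19.7 would be shared by chance (Fisher's exact test across genes, one-sided, p = 9.85e-99). They shared 10 lower genes out of 232 and 90, where 1.8 would be shared by chance (Fisher's exact test, p = 1.32e-05), Bcl2 among them. The comparisons have no library in common, but they share 1 fit and its estimate of spread for each gene. The p-values assume an independence that therefore does not hold. Of the 151 shared higher genes, 125 lay under 5 CPM in single MAIT cells, and the macrophage genes C1qa, Csf1r and Lyz2 were among these. Genes called in opposite directions numbered 1 and 9.

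The interaction term asked which responses to S. epidermidis differed between the cell types. Egr1 rose more in the MAIT libraries, with CD4 values of 73.5 and 86.3 RPKM before and after (difference of log2 changes 3.17, SE 0.16, adjusted p = 0.00238). That MAIT cells were its source is not shown, as stated above. Klf2 (chromosome 8, 72319062 to 72321654) went from 56.3 to 177 RPKM in MAIT cells and from 193 to 117 RPKM in CD4 T cells (difference 2.34, SE 0.26, adjusted p = 0.0197). Furin went from 990.2 ± 198 to 605 ± 74.6 RPKM in MAIT cells against its rise in CD4 T cells (difference -1.88, SE 0.25, adjusted p = 0.0233). Tnf went from 233 to 185 RPKM in MAIT cells (difference -1.64, SE 0.19, adjusted p = 0.0202), and Il23r, the IL-23 receptor gene, from 45.7 to 33.2 RPKM in MAIT cells and from 3.79 to 6.70 RPKM in CD4 T cells (difference -1.14, SE 0.18, adjusted p = 0.038).

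Type 17 genes as a list responded less in MAIT than in CD4 T cells (median difference -0.86, adjusted p = 0.000362, adjusted p = 0.55 with an estimated correlation). Il23r and Il17re (-1.66) passed, 2 of 20, and 13 adjusted over the list alone. They passed in 11 and 5 of 21 alternative settings. Differences for Il17a, Il17f and Il22 were -1.95, -2.68 and -3.29 and did not pass. Proliferation genes had a median difference of -0.67 (adjusted p = 0.000105, adjusted p = 0.55 with an estimated correlation), with 0 of 26 past the test and 9 adjusted over the list alone. Interferon-stimulated genes had a median difference of 0.40 (adjusted p = 0.00207, adjusted p = 0.55 with an estimated correlation), with 0 members past the test and 0 adjusted over the list alone. The macrophage list moved with these groups, at a median difference of 1.23 (adjusted p = 0.035, adjusted p = 0.55 with an estimated correlation), with Cst3 higher, C1qb lower, and 4 adjusted over the list alone. The C1qb difference starts from CD4 control values near the floor, as given above. After association C1qb stood at 1493 RPKM in the MAIT libraries and 191.8 RPKM in the CD4 libraries. Among called genes that met the rule for naming, the largest positive differences were Cd81 (4.22), Ms4a6b (4.13), Ms4a6c (3.6) and Ltc4s (3.52). The largest negative among them were Mcpt4 (-3.91, CD4 controls listed at 0, called in 10 of 20 settings), C1qb (-2.62), the histone gene Hist1h3c (-2.59) and Hyou1 (-2.51). Single MAIT cells of control mice held less Cd81 (5.57 CPM against 8.85) and Ms4a6b (133 against 150) than empty barcodes. Median, mean and test differed in sign for the type 2 (-0.04, -0.12, test upward), neutrophil (0.22, -0.08, upward) and keratinocyte (-0.19, 0.08, upward) lists. Plagl2, a zinc finger factor, went from 4.76 to 26.7 RPKM in CD4 T cells and stood at 9.97 and 9.47 RPKM in MAIT cells (difference -2.33, adjusted p = 0.0244).

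The interaction held 244 genes in limma, 129 with the larger log2 change in MAIT cells and 115 with the smaller (52.9% larger), and 2545 had an unadjusted p under 0.05. The median over all genes was -0.14 log2, and quantile normalization gave 237 and 131 (64.4% larger). The count was 1 without the first and 4 without the second S. epidermidis CD4 library, 4 and 3 without the first and second S. epidermidis MAIT library, and 90 and 61 without the first and second MAIT control library. It was 159 with edgeR and TMM, 1468 with DESeq2, and 416 (100 larger, 316 smaller) among genes read in single MAIT cells.

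**Figure D2:**
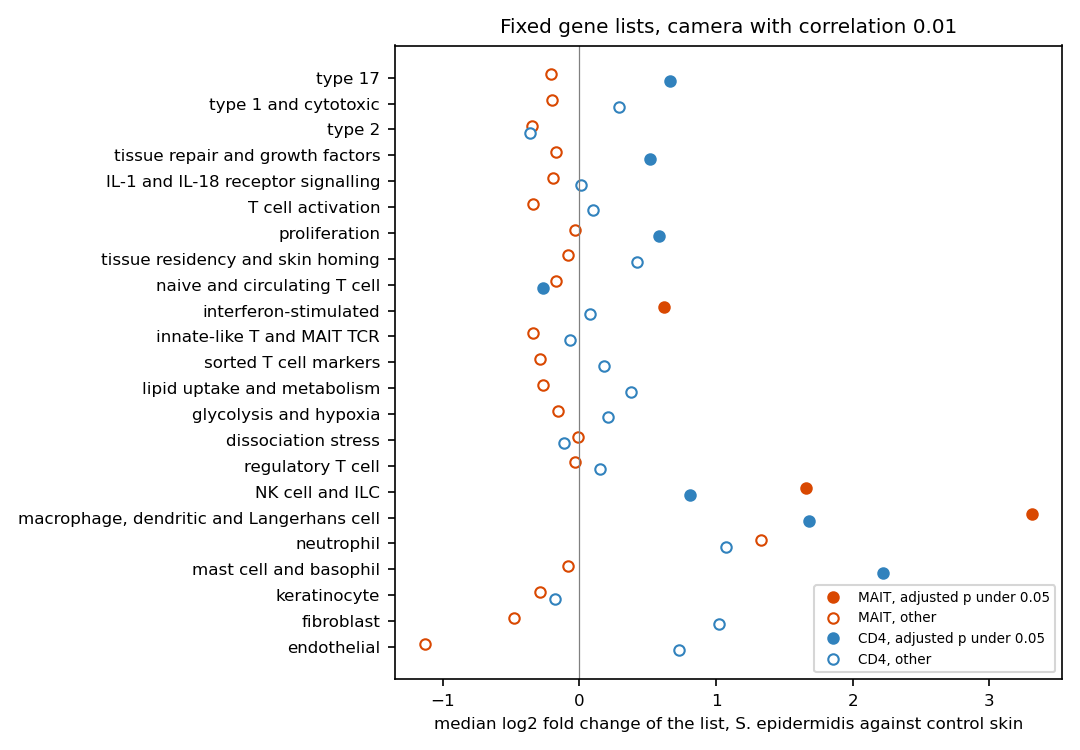
Median log2 change with S. epidermidis (x axis) of each of the 23 tested gene lists (y axis), orange for MAIT cells and blue for CD4 T cells, filled where the adjusted p in camera was under 0.05. The macrophage list lies farthest to the right for MAIT cells, at 3.31, and the type 17 list lies at -0.21 for MAIT cells and 0.66 for CD4 T cells.

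MAIT cells were next compared with CD4 T cells of control skin. MAIT cells were higher in Sdc1 (chromosome 12, 8771396 to 8793687), at 236 ± 9.20 against 9.64 ± 0.0969 RPKM (log2 difference 4.48, SE 0.10, adjusted p = 3.7e-06), and in the Src family kinase gene Blk, at 31.8 ± 6.89 against 0.259 RPKM (4.69, SE 0.19, adjusted p = 2.92e-05). CD4 T cells were higher in the co-stimulatory receptor gene Tnfrsf4, at 4179 ± 285 against 59.1 ± 20.5 RPKM (log2 difference -6.16, SE 0.22, adjusted p = 1.79e-05), in Ctla4, at 456 ± 2.30 against 2.33 ± 0.866 RPKM (-7.12, adjusted p = 4.3e-05), and in Cd5, a negative regulator of receptor signalling, at 165 ± 6.45 against 1.58 ± 0.730 RPKM (-6.03, adjusted p = 1.08e-05). Ifng was listed at 0 in both MAIT control libraries and at 19.99 and 24.12 RPKM in CD4 T cells.

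Type 17 genes were higher in MAIT cells in 15 of 20 members and lower in 0 (17 adjusted over the list alone, median 2.09, adjusted p = 2.5e-15, adjusted p = 0.1 with an estimated correlation), with Il23r at a log2 difference of 3.29 and Tmem176b at 1.78. Innate-like genes were higher in 3 of 6 members (4 adjusted over the list alone, median 0.63, adjusted p = 0.015, adjusted p = 0.317 with an estimated correlation), Zbtb16 (2.34) and Klrb1b (1.77) among them. Interferon-stimulated genes were lower in 7 of 19 (11 adjusted over the list alone, median -0.95, adjusted p = 0.000237, adjusted p = 0.344 with an estimated correlation). Glycolysis and hypoxia genes were lower in 8 of 18 and higher in 2 (12 adjusted over the list alone, median -0.36, adjusted p = 0.000551, adjusted p = 0.317 with an estimated correlation). Ldha stood at 1770 against 2987 RPKM and the glucose transporter gene Slc2a1 at 32.6 against 69.7 RPKM. Regulatory T cell genes were lower in 5 of 9 and higher in 1 (9 adjusted over the list alone, median -1.88, adjusted p = 0.00546, adjusted p = 0.317 with an estimated correlation). Foxp3, which overlaps Ccdc22, stood at 6.22 ± 0.286 against 158 ± 39.3 RPKM. Type 2 genes were lower in 4 of 9 and higher in 2 (7 adjusted over the list alone, median -1.32, adjusted p = 0.0216, adjusted p = 0.464 with an estimated correlation), with Gata3 at -1.32 and Il17rb at 1.73.

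Proliferation genes were lower in MAIT cells in 1 of 26 (0 adjusted over the list alone, median -0.27, adjusted p = 0.015, adjusted p = 0.717 with an estimated correlation). Dissociation stress genes were higher in 8 of 18 and lower in 2 (13 adjusted over the list alone, median 0.38, adjusted p = 0.0216, adjusted p = 0.516 with an estimated correlation), Fos (1.5) and Atf3 (1.54) among them. Markers of other cells moved with these groups. The mast cell list was higher in 4 of 7 (5 adjusted over the list alone, median 2.74, adjusted p = 0.000551, adjusted p = 0.38 with an estimated correlation), the macrophage list in 7 of 15 (7 adjusted over the list alone, median 0.40, adjusted p = 0.00164, adjusted p = 0.38 with an estimated correlation) and the NK cell list in 1 of 5 (1 adjusted over the list alone, median 0.88, adjusted p = 0.0432, adjusted p = 0.38 with an estimated correlation). Lists that did not pass still had calls both ways. The residency list had 3 higher and 5 lower of 16 (12 adjusted over the list alone, median -0.43), with Itgae (1.17) higher and Prdm1 (-2.45) lower. The type 1 list had 5 higher and 8 lower of 18 (14 adjusted over the list alone, median -0.53). The repair list had 6 and 4 of 23 (13 adjusted over the list alone, median 0.59, mean -0.08, test upward) and the activation list 5 and 7 of 21 (14 adjusted over the list alone, median 0.17, mean -0.61, test downward).

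Between the control sorts limma called 1778 genes, 890 higher and 888 lower in MAIT cells, with a median over all genes of 0.005 log2, and 3504 had an unadjusted p under 0.05. The count was 1123 without the second CD4 control library, 986 without the second MAIT control library, 620 with only the 2 groups in the fit and 3285 with DESeq2.

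After S. epidermidis, MAIT cells remained higher than CD4 T cells in Sdc1, at 188 ± 9.63 against 5.37 ± 0.228 RPKM (log2 difference 4.89, SE 0.10, adjusted p = 4.02e-06), and in Blk (4.74, SE 0.19, adjusted p = 4.06e-05). Mycn, a Myc family transcription factor, was at 26.3 ± 4.73 against 1.03 ± 0.380 RPKM (3.75, SE 0.20, adjusted p = 0.000156). CD4 T cells were higher in Tbx21, the type 1 lineage regulator, at 29.0 ± 4.68 against 0.2995 ± 0.4207 RPKM (log2 difference -4.56, SE 0.27, adjusted p = 2e-04), and in Ifng, at 31.6 ± 4.01 against 0.4085 ± 0.5777 RPKM (-4.59, SE 0.29, adjusted p = 0.00025).

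Type 17 genes were higher in MAIT cells in 13 of 20 members and lower in 2 (16 adjusted over the list alone, median 1.06, adjusted p = 1.45e-08, adjusted p = 0.238 with an estimated correlation). The cytokine genes Il17a and Il17f went against the list. By the means given above, both stood lower in MAIT than in CD4 libraries after association. Proliferation genes were lower in MAIT cells in 16 of 26 members (24 adjusted over the list alone, median -0.83, adjusted p = 8.33e-08, adjusted p = 0.478 with an estimated correlation), with Mki67 at 15.3 against 42.8 RPKM and Mcm6 at 59.0 against 112 RPKM. Glycolysis genes were lower in 13 of 18 (14 adjusted over the list alone, median -0.73, adjusted p = 9.23e-05, adjusted p = 0.238 with an estimated correlation), Ldha at 1469 against 2870 RPKM. Lipid genes were lower in 9 of 16 and higher in 1 (10 adjusted over the list alone, median -0.85, adjusted p = 0.0177, adjusted p = 0.478 with an estimated correlation), among them the fatty acid binding protein gene Fabp5, at 23.8 against 74.4 RPKM. Type 1 genes were lower in 10 of 18 and higher in 3 (14 adjusted over the list alone, median -1.67, adjusted p = 0.0177, adjusted p = 0.238 with an estimated correlation), and regulatory T cell genes lower in 5 of 9 and higher in 1 (7 adjusted over the list alone, median -1.78, adjusted p = 0.0315, adjusted p = 0.258 with an estimated correlation). Dissociation stress genes were higher in 8 of 18 and lower in 3 (11 adjusted over the list alone, median 0.56, adjusted p = 0.00202, adjusted p = 0.45 with an estimated correlation), with Jun at 2.54 and Fos at 2.44. The macrophage list moved with these groups, higher in 9 of 15 (10 adjusted over the list alone, median 2.03, adjusted p = 3.68e-09, adjusted p = 0.238 with an estimated correlation). So did the NK cell list (3 of 5, 3 adjusted over the list alone, median 1.08, adjusted p = 0.0035, adjusted p = 0.258 with an estimated correlation) and the mast cell list (0 of 7, 0 adjusted over the list alone, median 1.11, adjusted p = 0.0251, adjusted p = 0.521 with an estimated correlation). Median and test differed in sign for the IL-1 and IL-18 receptor (-0.06), naive (-0.06) and keratinocyte (-0.05) lists, whose tests pointed upward.

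After association limma called 2547 genes between the sorts, 981 higher and 1566 lower in MAIT cells (38.5% higher), with a median over all genes of -0.16 log2, and 4258 had an unadjusted p under 0.05. Quantile normalization gave 1223 and 1234 (49.8% higher), edgeR with TMM 903 and 733 (55.2%), RLE 56.6% and limma-voom 56.6%, so the side with more calls depends on the scaling. The count was 1138 and 940 without the first and second S. epidermidis CD4 library, and 1367 and 1009 without the first and second S. epidermidis MAIT library. Both skin conditions shared 384 genes higher in MAIT cells (76.2 by chance, Fisher's exact test across genes, one-sided, p = 1.92e-195) and 541 lower (121.4 by chance, p = 1.63e-267), with 26 and 18 in opposite directions and no library in common.

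In the single-cell library, 854 of the kept cells carried exactly 1 hashtag, 360 with HTO1, 11 with HTO2, 223 with HTO3 and 260 with HTO4. The tags differed in cell class. Of HTO3 cells 86.1% lay in the MAIT17-like cluster (exact 95% interval 80.9% to 90.4%), against 1.11% of HTO1 cells (0.303% to 2.82%) and 0.385% of HTO4 cells (0.00974% to 2.12%). Of HTO4 cells 56.9% (50.7% to 63.0%) lay in the MAIT1-like cluster and 9.23% (6.00% to 13.4%) in the naive T-like cluster, whereas 0 of 360 HTO1 cells lay in the MAIT1-like cluster, which allows a share of up to 0.833%. HTO1 cells were spread over unnamed clusters (88.3%, 84.6% to 91.5%) and cycling-like cells (10.6%, 7.58% to 14.2%). For HTO3, 0 of 223 cells were cycling-like, which allows a share of up to 1.35%. The unnamed clusters carried MAIT17 markers as well. Clusters 1 and 3 held 46.9% (41.7% to 52.3%) and 32.5% (27.7% to 37.6%) of HTO1 cells, and cluster 5 held 22.3% (17.4% to 27.9%) of HTO4 cells. HTO2 had 3 MAIT1-like, 1 MAIT17-like and 7 unnamed cells. Without genes of other cell types among the variable genes, a setting chosen after seeing the data, the naive T-like share of HTO4 was 4.62%. The MAIT17-like name depends on the cell filter. With at least 200 genes and at most 20% mitochondrial UMIs per cell no cluster met the naming rule for it, so its share was 0 in every tag, while the MAIT1-like share of HTO4 was 66.5%. Intervals and limits of a count of 0 cover counting error only, and with 1 library there are no replicates and no test. Of the 6162 kept cells, 5205 had no hashtag barcode. Cluster 7 held 6.49% of those 5205 cells, against 0.833% of HTO1, 1.79% of HTO3 and 0.385% of HTO4 cells. The tagged cells may therefore not stand for the rest.

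**Figure D3:**
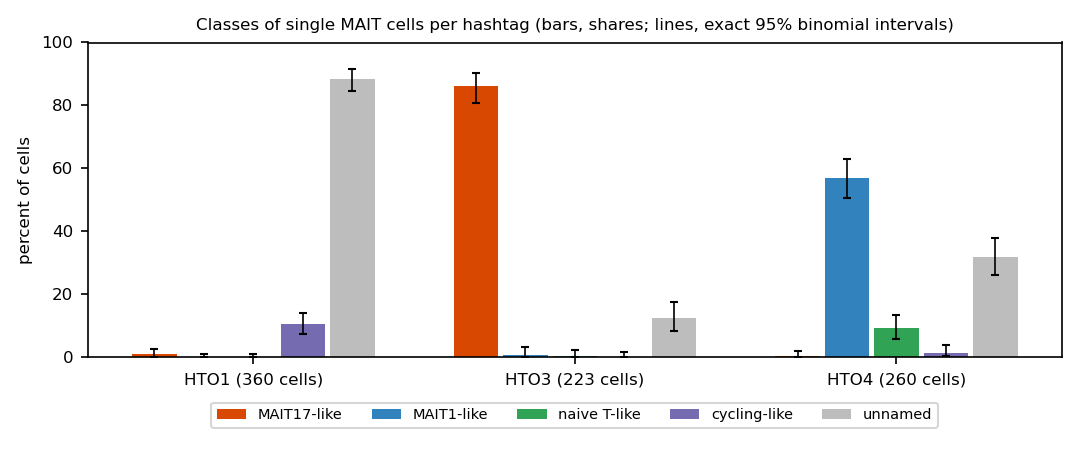
Percent of cells (y axis) in each class (x axis) for 360 HTO1, 223 HTO3 and 260 HTO4 cells, as bars from 0 with exact 95% binomial intervals as lines. The MAIT17-like class holds 86.1% of HTO3 cells and the MAIT1-like class 56.9% of HTO4 cells.

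Genes followed the same division. Il17a stood at 668 CPM in HTO3 cells (95% Poisson interval 613.9 to 726.5), 22.5 in HTO1, 46.1 in HTO2 and 5.51 in HTO4. With it the chemokine gene Cxcl2 (164 CPM), the heat shock gene Hspa1a (537), the leukotriene receptor gene Ltb4r1 (484) and Gadd45b (1016) were highest in HTO3. The dissociation stress list moved with them, at 12990 CPM in HTO3, 9826 in HTO1 and 7681 in HTO4. Erythroid transcripts summed to 1402 CPM there, against 17.3 in HTO1 and 26.6 in HTO4, but 1 cell held 98.5% of these UMIs. HTO1 cells were highest in Odc1, the rate-limiting enzyme of polyamine synthesis (1507 CPM against 255 in HTO3), in the lamin gene Lmna (2054 against 424), in the cell cycle inhibitor Cdkn1a (471 against 103) and in Stmn1 (572 against 85.4 in HTO4). HTO4 cells were highest in Slamf6, a receptor of the SLAM family (114 CPM against 2.40 in HTO1 and 3.62 in HTO3), and in Cd160 (248), Xcl1 (157), Gimap7 (228) and Dtx1 (217). Counts above all other tags held for 195 genes in HTO1, 41 in HTO3, 20 in HTO4 and 0 in HTO2, whose 43435 UMIs allow little. With each cell thinned to 2000 UMIs they held for 88 genes in HTO1, 19 in HTO3 and 13 in HTO4. A gene also had to lie above HTO2, whose 11 cells give wide intervals. Ccl5 was left out of the HTO4 count in this way, at 1424 CPM against 1440 to 2267 in HTO2, 52.3 in HTO1 and 77.2 in HTO3. These counts therefore do not rank the tags.

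Summed lists differed by tag as well. The type 17 list stood at 6410 CPM in HTO3, 4231 in HTO1 and 1889 in HTO4, and within it Rora was highest in HTO1 (1112 CPM) while Ramp1 (1194) and Tmem176b (993) were highest in HTO3. The type 1 list stood at 4626 CPM in HTO4, 1819 in HTO1 and 1168 in HTO3, with Ccl5 at 1424, 52.3 and 77.2 CPM and Ms4a4b at 979, 9.59 and 66.4 CPM, but within it Klrk1 was at 149, 397 and 147 CPM and Nkg7 at 834, 770 and 442 CPM. The NK cell list moved the same way, at 220 CPM in HTO4, 110 in HTO1, 21.7 in HTO3 and 322 in HTO2. The 11 HTO2 cells stood above HTO4 for the type 1 list (6216 CPM, 5497 to 7004) and at 3200 CPM for the type 17 list, with Ccl5 at 1819 CPM (1440 to 2267). Ccl5 was read in only 36.4% of the HTO2 cells, and the intervals leave out the spread between cells. Repair genes stood at 2029 CPM in HTO1, 1120 in HTO3 and 471 in HTO4. Among them Furin was at 808, 393 and 66.1 CPM, Tgfb1 at 483, 226 and 149 CPM, Anxa1 at 302, 121 and 30.3 CPM and the growth factor gene Areg at 95.9, 57.9 and 2.75 CPM. Residency genes stood at 4446 CPM in HTO3, 4090 in HTO1 and 2328 in HTO4. Among them Itgae stood at 208, 65.2 and 31.2 CPM in HTO1, HTO3 and HTO4, and Cxcr6 at 1664, 1470 and 980.4 CPM, while Rgs2 (875 CPM) and Selplg (829) were highest in HTO3. The naive list stood at 3069 CPM in HTO4, 2232 in HTO3 and 1710 in HTO1. Within it Klf2 stood at 387 CPM in HTO4, 135 in HTO3 and 49.4 in HTO1, and Il7r at 1080, 1191 and 584 CPM, with HTO2 at 1335, while Satb1 was highest in HTO1 (445 CPM against 340 in HTO4). Keratinocyte transcripts reached 173 CPM in HTO1, 39.8 in HTO3 and 45.0 in HTO4, against 296 in empty barcodes, and mast cell transcripts were 0 in all 4 tags.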

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

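All tests of explanations in this part were chosen after the result was seen, and 2 of them were redrawn after a first outcome, as stated where they stand. The response to S. epidermidis differed between MAIT and CD4 T cells for 244 genes by the interaction term in limma. Among named genes the difference of log2 changes was positive for Cd81 (4.22), Ms4a6b (4.13), Ms4a6c (3.6), Ltc4s (3.52), Fam212a (3.27), Egr1 (3.17), Hfe (3.07), Cd200r1 (2.93), Ctss (2.84), Trf (2.82), Metrnl (2.81), Ppbp (2.76, but -2.44 with edgeR and TMM, -2.43 with RLE, -2.49 with library size only and -1.83 with DESeq2), Klf2 (2.34), Il6ra (2.00), Cst3 (1.37), Dusp1 (1.23) and Cd4 (1.18). It was negative for Mcpt4 (-3.91), C1qb (-2.62), Hist1h3c (-2.59), Hyou1 (-2.51), Irgq (-2.42), Plagl2 (-2.33), Gja1 (-2.29), Nbeal2 (-2.19), Snrnp200 (-2.03), Cluh (-1.99), Abca2 (-1.97), Zfp280b (-1.90), Furin (-1.88), Il17re (-1.66), Tnf (-1.64), Pdgfb (-1.61), Hsph1 (-1.15) and Il23r (-1.14). The C1qb difference starts from CD4 control values near the floor. In the hashtag library 170 barcodes that are not called cells carried 1 hashtag, 1 with HTO1, 17 with HTO2, 55 with HTO3 and 97 with HTO4, out of 1003 such barcodes.

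Macrophage transcripts were higher in the S. epidermidis libraries of both sorts, at list medians of 3.31 in MAIT cells and 1.68 in CD4 T cells. A lower share of T cells with all other skin cells raised alike is argued against in the MAIT sort. There the keratinocyte, fibroblast and endothelial lists (9, 6 and 4 genes) had medians of -0.29, -0.48 and -1.13 (SD 0.59, 0.48 and 1.34). It stays open in the CD4 sort, where the largest of these medians was 1.02 (SD 0.80) and the macrophage list varied widely (SD 2.89). A T cell share lowered by macrophages alone would leave these lists unmoved, so they cannot decide on it. Macrophage RNA, more of it after S. epidermidis, may account for part of the MAIT change, since 71.2% of the genes that rose lay under 5 CPM in single MAIT cells against 32.3% of tested genes, though those cells came from control mice and cannot exclude induction in MAIT cells. RNA of 1 kind added to both sorts is argued against as the sole source of the 125 genes that rose in both and lay under 5 CPM in single MAIT cells. Their log2 ratios of MAIT to CD4 had an SD of 1.23 against a replicate spread of 0.32. The screen used MAIT cells only, so transcripts made by CD4 T cells would widen these ratios too. The lowest were Ermn (-4.09) and Gm16894 (-2.82), against a median of 2.41. The low ratios were not limited to these genes, with Tlr2 at -0.18, Clec4d at 0.42, Hmox1 at 0.61 and Ccl2 at 0.90. At the other end Chp2 stood at 4.13. Which cells made each gene is not known, so this test cannot decide on macrophage RNA of 1 kind in both sorts. A redrawn test on the 9 genes of the macrophage list gave an SD of 0.49 against 0.28, and there it stays open. The sort gates (CD45, Thy1.2 and TCRb) are meant to leave macrophages out, but how far they kept out these cells or their RNA was not tested. Lyz2 had a mean of 5543 RPKM in the S. epidermidis MAIT libraries, against 233 RPKM for Cd3e. A biological response of the sorted cells to the association was not tested and stays open.

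Type 17 genes as a list changed less in MAIT cells than in CD4 T cells, by a median of -0.86. Only 2 of 20 members passed, and camera with an estimated correlation gave an adjusted p = 0.55. The scaling of the libraries is argued against as the cause, since the median was -0.758 under quantile normalization. Dilution of MAIT RNA by other RNA cannot be told apart, since the 9 sorted T cell markers had a median difference of -0.17 with an SD of 0.69 and a lowest value of -1.04, which spans the type 17 median. This bound was widened to 2 SD after the outcome was seen. At 1 SD the explanation would have been argued against, by a margin too small to show in the printed values. A biological difference between the cell types stays open and was not tested further.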

How the results depend on the processing

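Alternatives on recovered multiples, on single-cell detection and with the macrophage covariate were chosen after seeing the data. The cause of each move was not tested, except where the alternative uses fewer genes or samples. Over 321 named-gene results, 5572 alternative values kept direction and call, 1295 kept direction and lost the call, and 4 reversed. All 4 are the Ppbp interaction (2.76), at -2.44 with edgeR TMM, -2.43 with RLE, -2.49 with library size only and -1.83 with DESeq2, with CD4 controls listed at 0. Among all 244 interaction calls, 13 turned sign with edgeR under each scaling and with DESeq2, 16 with limma-voom and 2 with a pseudocount of 0.1. Under the covariate, which is collinear with the groups, 98 of the MAIT calls, 18 of the CD4 calls, 1 between control sorts and 97 between S. epidermidis sorts turned sign, and single genes were not followed.

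For S. epidermidis in MAIT cells (882 genes) edgeR gave 462 with TMM, 458 with RLE and 464 with library size only, DESeq2 1487, genes detected in single MAIT cells 395, the covariate 4, and left-out libraries 372 to 891. In CD4 T cells (437) no filter gave 102, only the 2 groups 48, limma-voom 268, DESeq2 2055, the covariate 5, and left-out libraries 42 to 392. For the interaction (244) quantile normalization gave 368, a pseudocount of 0.1 gave 122, edgeR (all 3 scalings) and limma-voom 159 each, DESeq2 1468, genes detected in single MAIT cells 416, the covariate 21, and left-out libraries 1 to 228. Between control sorts (1778) only the 2 groups gave 620, DESeq2 3285, the covariate 265, and left-out libraries 986 to 1538. Between S. epidermidis sorts (2547) edgeR gave 1636 with TMM and 1631 with RLE, the covariate 24, and left-out libraries 940 to 2821. A lone library is assumed to vary like the other groups. Other settings, the replicate block apart, stayed within 1.5 times the count.

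Replicate numbers do not pair the samples (correlations -0.011 to 0.042). A replicate block gave 787, 316, 90, 1566 and 2283 genes, in the order above. Lists past camera numbered 3, 7, 4, 11 and 10, and 0 in all 5 with an estimated correlation. Fry gave 2 for the interaction and 16 between S. epidermidis sorts.

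In single cells, resolution 1.0 gave MAIT17-like shares of 0% for HTO1, 80.3% for HTO3 and 0% for HTO4. The looser filter (200 genes, 20% mitochondrial) left that class unnamed (0% in HTO1, HTO3 and HTO4) and gave a MAIT1-like share of 66.5% for HTO4. Without other-cell genes among the variable genes the naive T-like share was 0% for HTO3 and 4.62% for HTO4. Single-tag barcodes numbered 846 by the ratio rule and 851 at quantile 0.95. With cells thinned to 2000 UMIs, genes above all other tags numbered 88 for HTO1, 19 for HTO3 and 13 for HTO4. HTO2, with 11 cells, is limited by depth, and its wide intervals limit the counts of the other tags.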

Other observations

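The tests of explanations in this part were chosen after the result was seen, as were the genes in its first paragraph, which are those read at 5 CPM or more in single MAIT cells. Among them, MAIT libraries after S. epidermidis were higher in the metallothionein genes Mt1 (log2 change 4.09) and Mt2 (3.35), in Apoe (4.13) and in Ifitm3 (3.44), and lower in Selp, the gene of P-selectin (-2.89), the cytotoxic granule gene Gzmb (-1.94) and Tnfsf11. Empty barcodes held more Mt1 (68.2 CPM against 22.6), Mt2 (45.1 against 16.9), Apoe (42 against 15.6) and Ifitm3 (27.4 against 7.87) than single MAIT cells, so this reading does not show that MAIT cells express them, and the macrophage list rose in the same libraries (median 3.31). CD4 T cell libraries after S. epidermidis were higher in Cxcl2 (2.96), a neutrophil chemokine gene, and lower in Calca (-1.64), the gene of the neuropeptide CGRP. Gzmb (172 CPM against 135), Cxcl2 (49.6 against 28.5), Calca (55.8 against 30.5) and Il17a (197 against 160) were higher in empty barcodes too. Tnfsf11 was nearly equal (174 against 173), and Selp went the other way (4.43 against 5.15). The comparison with empty barcodes therefore cannot decide which genes MAIT cells express.

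A single-cell cluster of 348 T cells held 152 cells with 2 or more UMIs of the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1, with Cd74 at 1522 CPM against 44.9 in other clusters and H2-Ab1 at 351 against 12.6. The cluster was taken for its high Cd74 and the cells for these same transcripts, so this excess follows from the choice. The most of these UMIs in 1 T cell was 875, so single cells can carry much of a sum. These 152 cells had Cd3e at 363 CPM against 358, Il17a at 437 against 136, and median UMIs of 6167 against 4435, while the other 196 cells of the cluster had Il17a at 538 CPM, Cd74 at 39.1 CPM and median UMIs of 4166. Doublets with antigen-presenting cells are argued against as the only cause, since 1.974% of the cells (0.409% to 5.66%) had a transcript of the other genes of such cells, with Cst3 taken off that list after its values were seen. Of the 6 of these cells with a hashtag barcode, 1 was a multiplet (16.7%, 0.421% to 64.1%), against 7.08% in other clusters, which is too few cells to decide. Free RNA is argued against as the only source, since 64 of all 6154 T cells (45 of them in this cluster, and 62 without those other genes) had 10 or more of these UMIs, against 0.00176 expected at the level of the empty barcodes and 29.5 at 5 times that level, a test that replaced one on cells chosen by the same transcripts. The design gives no biological explanation to test, and none was tested.

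Of the 6463 called cells, 5 were set apart by their macrophage transcripts (29137 UMIs in all), and 119 genes marked them. Their level was not compared with that of macrophages.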
